A study of Mus musculus with 12 samples.

How the data were processed

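The 12 samples are polyribosomal RNA libraries from mouse hippocampus. Per the labels' protocols, homogenates were cleared by 2 low-speed spins, the supernatant was spun for 4 h through a 1 molar sucrose cushion, RNA was purified from the pellet, libraries were made with the SMARTer total RNA-seq kit and sequenced on an Illumina NextSeq500 as 40 bp read pairs. A cushion pellet holds RNA bound to ribosomes and any other RNA that sediments as fast, and no input RNA was analysed here, so a change in level cannot be parted into a change in transcript amount and a change in ribosome association.

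The deposited files hold whole-number counts per gene symbol, one file per library, without normalization. The submitters' processing notes name cutadapt, TopHat, Bowtie and HTSeq and the genome build mm10. Tool versions, the gene annotation and whether counting used strand are not given in the sources used here. Each file lists 24421 genes and the summary lines of the counter, which were kept out of library sizes and tests. Of the counts assigned to a gene, to no gene or to several genes, 25.5% to 33.3% fell on no gene and 0.453% to 0.550% were ambiguous. A further 67.8 M to 115 M alignment records per library were set aside as not unique, so genes with near-identical copies are undercounted. Gene symbols were matched to GENCODE vM21 (GRCm38, the same assembly as mm10) for coordinates, and 23376 of the 24421 symbols were found there.

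Samples were grouped by their sample group label into 6 control and 6 fear case libraries, and there is 1 comparison. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), libraries were scaled by TMM, and fear case was compared with control by edgeR's quasi-likelihood test (estimateDisp, glmQLFit, glmQLFTest) without covariates, with Benjamini-Hochberg adjustment over the 14564 genes tested and calls at an adjusted p under 0.05. The standard error is the log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes, and log2 CPM a prior count of 2. Depth sets the precision: at the median of 21.6 M counts, 1 CPM is 21.6 counts, and a gene needs about 10 counts in 6 libraries to be tested.

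Before the data were examined, 29 gene lists were fixed from background knowledge. They were rapid immediate early genes, later activity-regulated genes, cytosolic ribosomal proteins, translation factors, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, postsynaptic glutamatergic genes, presynaptic and vesicle genes, FMRP-bound long neuronal mRNAs, markers of GABAergic interneurons, dentate gyrus, CA1 and CA2, CA3, oligodendrocytes, astrocytes, microglia, endothelial and mural cells, choroid plexus and ependyma, blood cells, thalamus, and cortex and striatum, heat shock and chaperones, ATF4 and integrated stress response targets, glucocorticoid-responsive genes, nuclear-retained long noncoding RNAs, snoRNA host and TOP noncoding RNAs, structural noncoding RNAs, replication-dependent histones, and sex-linked checks. Lists with at least 3 tested members were tested by camera with a preset correlation of 0.01, with an estimated correlation beside it, and by fry, with adjustment over the 27 lists. The choroid plexus score is the mean log2 CPM of the 17 tested members of that list other than the ciliated-cell genes Foxj1, Ccdc153 and Tmem212. Bdnf is in the later list and Arc, Fos and Npas4 in the rapid list.

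Genes were named by a rule fixed at the same time: among called genes with a mean of at least 1 CPM, up to 12 per direction by fold change, filled to 10 by the lowest unadjusted p and then said not to pass; always Fos, Arc, Egr1, Junb, Npas4, Nr4a1, Dusp1 and Bdnf; up to 4 members of each called list and 2 of each other list by lowest p; the 5 most abundant genes; and the sex-linked checks. Of the genes that the rule takes, 3 are not reported here. Other genes named (Ttr, Slc4a5, Folr1, Uba1y, Prdx2 and those of the 2 added lists) were chosen after their values were seen.

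Library make-up and principal component scores were compared by exact two-sided permutation tests over all 924 relabellings. The quasi-likelihood and list tests were tested on simulated data, with counts drawn from the means and library sizes of the real samples and 50 genes changed at each of 4 sizes among 14564 genes. They recovered 70% of genes changed 1.5-fold, 80% at 2-fold, 94% at 3-fold and 94% at 4-fold, with 14 unchanged genes called. A list shifted by 0.5 on the log2 scale was called along with 0 of the other lists. No correlation between genes and no library that stands apart from its group was built into these counts. The recovered shares therefore need not hold for the real libraries. In the real data the estimated correlation ranged from -0.0276 (snoRNA host and TOP noncoding RNAs) to 0.637 (choroid plexus and ependyma markers). The simulation therefore cannot show how often the preset correlation calls unchanged lists whose genes vary together. All 30 pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom of at least 8.09), so none was counted as a duplicate.

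Alternatives were other size factors (RLE, upper quartile, library size only), DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample weights, robust dispersions, no filter on low counts, a filter of 1 CPM in 6 libraries, the replicate number as a block, 1 surrogate variable (sva 3.50.0), the library number as a covariate, structural RNAs removed, a prior count of 0.5, and each library left out in turn. After the data were examined, 3 were added: the choroid plexus score as a covariate, fear case 6 thinned to 21.2 M counts, and control 6 and fear case 6 both left out. Lists of motile cilia and leptomeningeal fibroblast genes were also added then, the former with and without Tekt1, Rsph4a and Foxj1. Of 462 splits of the libraries into 6 and 6, 100 were drawn, the real one included. Scripts for coordinates and figures ran in Python 3.11.15.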

Results

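Polyribosomal RNA, the transcripts that sediment with ribosomes, was profiled in the hippocampus of 6-week-old C57/Bl6 mice. The 12 libraries fall into 2 groups by their labels, 6 control and 6 fear case. The protocol text is worded alike for every library and describes 8 min in an unfamiliar context, 7 min back in the home cage and tissue collection at 15 min. What the control mice experienced is not given in the labels. The series title names exposure to a new context while the group label and design text name fear, and whether a shock was given is not stated. The labels number the libraries within each group without stating that each came from a separate mouse, so the p-values measure the spread between these samples. Counts assigned to genes ranged from 18.6 M to 44.2 M per library with a median of 21.6 M, and 17035 to 18940 genes had at least 1 count. Fear case 6 was the deepest at 44.2 M, ahead of fear case 2 at 24.2 M. Among the most abundant genes by mean level were Rn45s (the 45S ribosomal RNA precursor), Malat1, Lars2 and Rpph1. Rn45s took 12.5% of the gene counts in fear case 6 and 4.55% to 7.98% in the other libraries.

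The comparison of fear case with control asks which transcripts differ on hippocampal polyribosomes between the groups as labelled, at the stated collection time. Of 35 tested rapid immediate early genes, which neurons switch on within minutes of activity, 6 rose in fear case and 29 did not pass, and 10 of the 35 had a negative log2 fold change. Fos, a subunit of the AP-1 transcription factor, rose 4.76-fold, from 4.38 ± 1.597 to 20.9 ± 7.21 CPM (scaled counts relative to library size; mean ± SD, n = 6 per group). Npas4, an activity-dependent transcription factor of neurons, rose 4.17-fold, from 5.12 ± 1.34 to 21.4 ± 4.62 CPM. The mean log2 CPM of 17 markers of the choroid plexus, the secretory epithelium of the brain ventricles, lay lower in 5 of the 6 fear case libraries than in any control.

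Of 14564 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 15 were called, 7 higher and 8 lower in fear case. At an unadjusted p under 0.05 there were 1040 genes, where 728 would be expected by chance. The 7 genes that rose were 6 immediate early genes and Malat1. The log2 fold change of Fos was 2.25 (SE 0.23, adjusted p = 1.1e-05) and that of Npas4 was 2.06 (SE 0.16, adjusted p = 3.0e-07). Fosb, another AP-1 subunit, rose by 1.03 on the log2 scale (SE 0.17, adjusted p = 0.00968). Btg2, an antiproliferative regulator of mRNA decay, rose by 0.91 (SE 0.11, adjusted p = 0.000235). Arc, a postsynaptic protein that acts in glutamate receptor trafficking, rose by 0.80 (SE 0.10, adjusted p = 0.000356), from 87.6 ± 13.6 to 153 ± 24.0 CPM. The AP-1 gene Junb rose by 0.79 (SE 0.10, adjusted p = 0.000478). For each of these 6 genes, all 6 fear case libraries lay above all 6 controls.

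**Figure D1:**
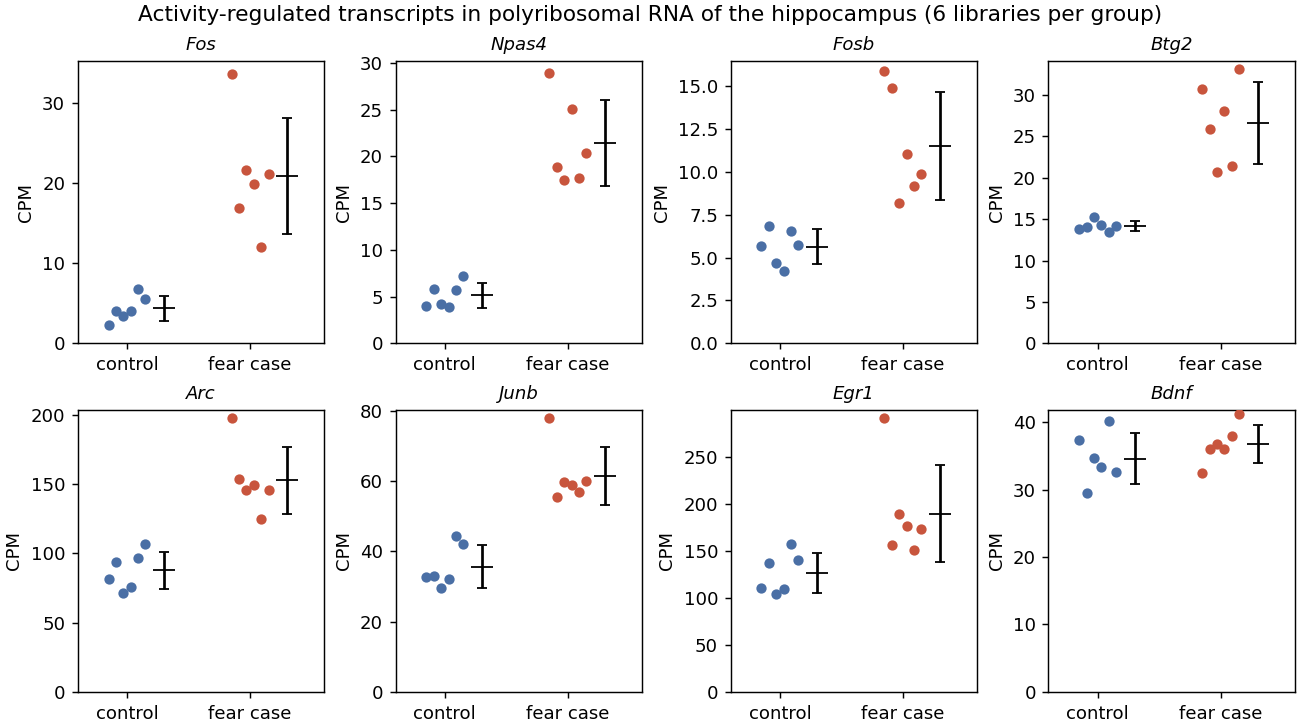
CPM (vertical axes, from 0) of 8 activity-regulated genes in each control and fear case library, with the group mean and SD as a bar beside the points (n = 6 per group). For Fos, Npas4, Fosb, Btg2, Arc and Junb the lowest fear case library lies above the highest control, whereas the groups overlap for Egr1 and Bdnf, which did not pass the test.

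The rapid immediate early gene list as a whole stood higher. Of its 35 tested members, 6 rose, 0 fell and 29 did not pass over all genes, while 17 were higher when adjusted over the list alone. The list test (camera) gave an adjusted p of 3.3e-30 with the preset correlation and 0.0418 with an estimated correlation. It was the only one of the 27 tested lists whose call held with an estimated correlation. Among members that did not pass over all genes, Ier2 had a log2 fold change of 0.96 (adjusted p = 0.0672), the phosphatase gene Dusp1 of 0.75 (adjusted p = 0.108) and the zinc-finger transcription factor gene Egr1 of 0.58 (adjusted p = 0.108). The orphan nuclear receptor gene Nr4a1 had a log2 fold change of 0.34 (SE 0.12, adjusted p = 0.452). The median over the list was 0.14. By contrast, 0 of the 30 tested members of the later activity-regulated list passed, over all genes or adjusted over the list alone (adjusted p of the list 0.229, and 0.601 with an estimated correlation). With edgeR 3 of them had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Bdnf, a neurotrophin gene of that list, had a log2 fold change of 0.09 (SE 0.09, adjusted p = 0.859).

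In the GRCm38 annotation, Fos lies on chromosome 12 from 85473890 to 85477273 on the plus strand, Npas4 on chromosome 19 from 4984355 to 4990316 on the minus strand, and Arc on chromosome 15 from 74669083 to 74672570 on the minus strand. No exon of these 3 genes overlaps an exon of another counted gene. Exons of Junb (chromosome 8, 84974484 to 84978718, minus strand) overlap exons of Prdx2 on the opposite strand. Whether the counting used strand is not given in the sources used here. Reads from the overlap may have been set aside as ambiguous or counted to either gene, so its effect on the Junb counts is not known. The same holds for Dusp1 with Ergic1, Ucp2 with Dnajb13, Ppp1r1b with 1700003D09Rik, Slc4a2 with Fastk and Pltp with Ctsa.

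Malat1, an abundant nuclear long noncoding RNA, rose by 0.55 on the log2 scale (SE 0.10, adjusted p = 0.0280), and 5 of 6 fear case libraries lay above all controls. Leaving out any one of control 1, control 2, control 3, control 4, fear case 2 or fear case 5 ended this call, as did the choroid plexus covariate described below, and its log2 fold change stayed between 0.47 and 0.61 over all 28 alternative settings. The nuclear-retained long noncoding RNA list was not called (adjusted p = 0.195, and 0.601 with an estimated correlation). Malat1 was its only member to pass of 11 tested, and 2 members were higher when adjusted over the list alone. Its test and mean were positive while its median log2 fold change was -0.11. With one library left out that median ranged from -0.24 without fear case 2 to 0.07 without control 1, the only such setting with a positive median. That list was called without control 1 (adjusted p = 0.0443), without fear case 1 (0.0260) or without fear case 3 (0.0263), and its direction turned without fear case 2 (0.986).

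The 8 genes that fell were not members of the neuronal activity lists, and 7 of them are described here. Msx1, a homeobox transcription factor gene, fell by 1.36 on the log2 scale (SE 0.22, adjusted p = 0.00700), from 22.04 ± 5.36 to 8.50 ± 3.79 CPM. Ppp1r1b, which encodes a protein phosphatase 1 inhibitor regulated by dopamine, fell by 0.76 (SE 0.11, adjusted p = 0.00224). Nxn, which encodes the redox protein nucleoredoxin, fell by 0.70 (SE 0.12, adjusted p = 0.0112). Tekt1, a component of ciliary microtubules, the mitochondrial uncoupling protein gene Ucp2, the anion exchanger gene Slc4a2 and 5930403L14Rik fell by 0.60 to 1.02, each with an adjusted p of 0.0483. All 6 fear case libraries lay below all controls for Msx1, Ppp1r1b, Nxn and 5930403L14Rik, and 5 of 6 did so for Tekt1, Ucp2 and Slc4a2. Gm11744 and Rsph4a, a radial spoke gene of motile cilia, came next with log2 fold changes of -0.97 (adjusted p = 0.0539) and -0.70 (adjusted p = 0.0722). The calls of Tekt1, Ucp2, Slc4a2 and 5930403L14Rik each ended when 9 or more of the single libraries were left out in turn.

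Choroid plexus and ependyma markers were the list with the largest shift. Their median log2 fold change was -1.52 over 19 tested members, of which 18 had a negative value, and -2.54 without fear case 6. With edgeR 0 members passed over all genes, while 16 had an unadjusted p under 0.05 and 16 were lower when adjusted over the list alone. DESeq2 called 2 members and limma-voom 0. The list test gave an adjusted p of 8.1e-32 with the preset correlation and 0.0547 with an estimated correlation. Ttr, the choroid plexus transcript of the thyroid hormone carrier transthyretin, ranged from 641 to 1978 CPM in the controls. In fear case 1 to 5 it stood at 335, 7.41, 73.5, 7.96 and 210 CPM, and in fear case 6 at 1319 CPM. Kl, which encodes the hormone co-receptor klotho, averaged 50.8 ± 12.2 CPM in controls and 25.1 ± 17.4 CPM in fear case (log2 fold change -0.9996, SE 0.27, adjusted p = 0.218). Foxj1, the master regulator of motile cilia, had a log2 fold change of -0.66 (SE 0.14, adjusted p = 0.0759). The mean log2 CPM of 17 epithelial members was 3.05 to 3.98 in the controls and -1.28 to 2.12 in fear case 1 to 5, against 3.66 in fear case 6.

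**Figure D2:**
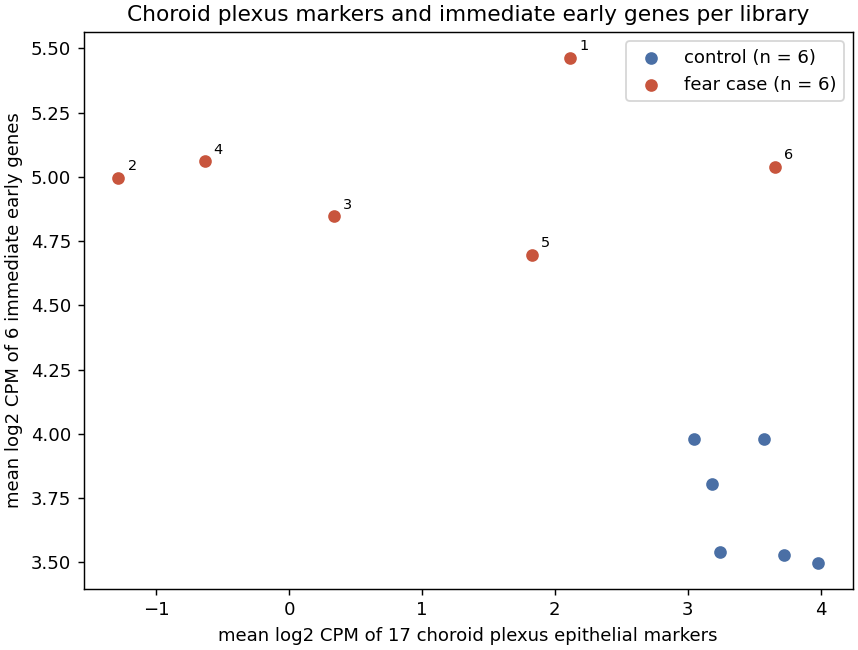
Mean log2 CPM of 17 choroid plexus epithelial markers (horizontal axis) against mean log2 CPM of 6 immediate early genes (Fos, Npas4, Arc, Junb, Fosb and Btg2; vertical axis) in the 12 libraries, with fear case libraries numbered. All 6 fear case libraries lie above the controls on the vertical axis, which follows from the choice of 6 genes called higher in this comparison. Of the fear case libraries, fear case 6 alone (3.66) lies within the control range of 3.05 to 3.98 on the horizontal axis.

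Without fear case 6, 128 genes were called, 12 higher and 116 lower. Of the 12 higher genes, 11 were rapid immediate early genes and the other was Malat1. Of the 116 lower genes, 16 were members of the choroid plexus list, which holds 20 genes, 19 of them tested in the main comparison. So short a list does not show whether the other lower genes belong to that tissue. With the choroid plexus score as a covariate, an alternative chosen after the data were examined, 5 genes were called, all higher: Fos, Npas4, Btg2, Arc and Junb. None of the 8 lower genes then passed, with adjusted p from 0.210 for Nxn to 0.689 for Slc4a2. The log2 fold change of Nxn was then -0.82 (SE 0.18), and those of the other 7 lay between -0.31 and -0.76. Fosb and Malat1 also lost their calls with this covariate, at log2 fold changes of 0.92 (SE 0.23, adjusted p = 0.522) and 0.59 (SE 0.14, adjusted p = 0.432). Of single libraries left out besides fear case 6, control 3 and fear case 2 had the most effect, with 9 genes called and 3 lower in each case. The lower genes numbered 4 without control 1, control 5, fear case 3, fear case 4 or fear case 5.

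Beyond these lists, 8 others were called with the preset correlation, and none of the 8 with an estimated correlation. No member of them passed with edgeR, over all genes or adjusted over the list alone, or with DESeq2 or limma-voom. Members with an unadjusted p under 0.05 numbered from 0 in the dentate gyrus list to 11 in the oxidative phosphorylation list. Nuclear-encoded oxidative phosphorylation genes had a median log2 fold change of -0.10 (63 of 74 negative; adjusted p = 9.4e-07, and 0.601 with an estimated correlation). Examples were Sdhc at -0.25 (adjusted p = 0.311) and Ndufa1 at -0.33 (adjusted p = 0.397). Cytosolic ribosomal protein genes had a median of -0.08 (71 of 79 negative; adjusted p = 4.8e-06, and 0.601 with an estimated correlation). Rpl41 stood at -0.15 and Rpl37 at -0.19, both with an adjusted p of 0.559. The FMRP-bound list, long neuronal mRNAs bound by the fragile X protein, had a median of 0.09 (47 of 59 positive; adjusted p = 1.6e-05, and 0.601 with an estimated correlation), with Trio at 0.19 (adjusted p = 0.524) and Usp9x at 0.22 (adjusted p = 0.597). Dentate gyrus markers had a median of 0.08 (14 of 15 positive; adjusted p = 0.00791, and 0.245 with an estimated correlation), with the granule cell transcription factor gene Prox1 at 0.13 (adjusted p = 0.747). Without fear case 6 the median was -0.04 for both the oxidative phosphorylation and the ribosomal protein list and 0.05 for the FMRP-bound list. It was -0.05 for the ribosomal protein list without control 3, and 0.05 for dentate gyrus markers without control 6 or without fear case 3.

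Replication-dependent histone genes had a median log2 fold change of -0.17 (18 of 18 negative; adjusted p = 0.000728, and 0.601 with an estimated correlation), with Hist1h4h at -0.26 (adjusted p = 0.613). Endothelial and mural markers had a median of -0.21 (17 of 20 negative; adjusted p = 0.00791, and 0.460 with an estimated correlation), with the phospholipid transfer protein gene Pltp at -0.79 (adjusted p = 0.559). Oligodendrocyte markers had a median of -0.11 (16 of 22 negative; adjusted p = 0.0268, and 0.601 with an estimated correlation), with the myelin genes Mobp at -0.26 (adjusted p = 0.618) and Mbp at -0.17 (adjusted p = 0.709). Of these 8 calls, 5 ended when a single library was left out, and without fear case 6 only 6 lists were called in place of 10. Those of the oxidative phosphorylation list (adjusted p = 0.117) and the histone list (0.0797) ended without fear case 6. The endothelial and mural call ended without fear case 1 (0.0686) or fear case 5 (0.0867). The oligodendrocyte call ended without control 3 (0.328), control 4 (0.0951), control 5 (0.257), fear case 1 (0.186), fear case 2 (0.124), fear case 5 (0.0571) or fear case 6 (0.110). The other was the call of the sex-linked checks (0.110 without fear case 6). The histone median was -0.10 without fear case 2 or fear case 6, that of endothelial and mural markers -0.13 without fear case 5 and -0.31 without fear case 6, and that of oligodendrocyte markers -0.06 without control 3 and -0.05 without fear case 1.

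**Figure D3:**
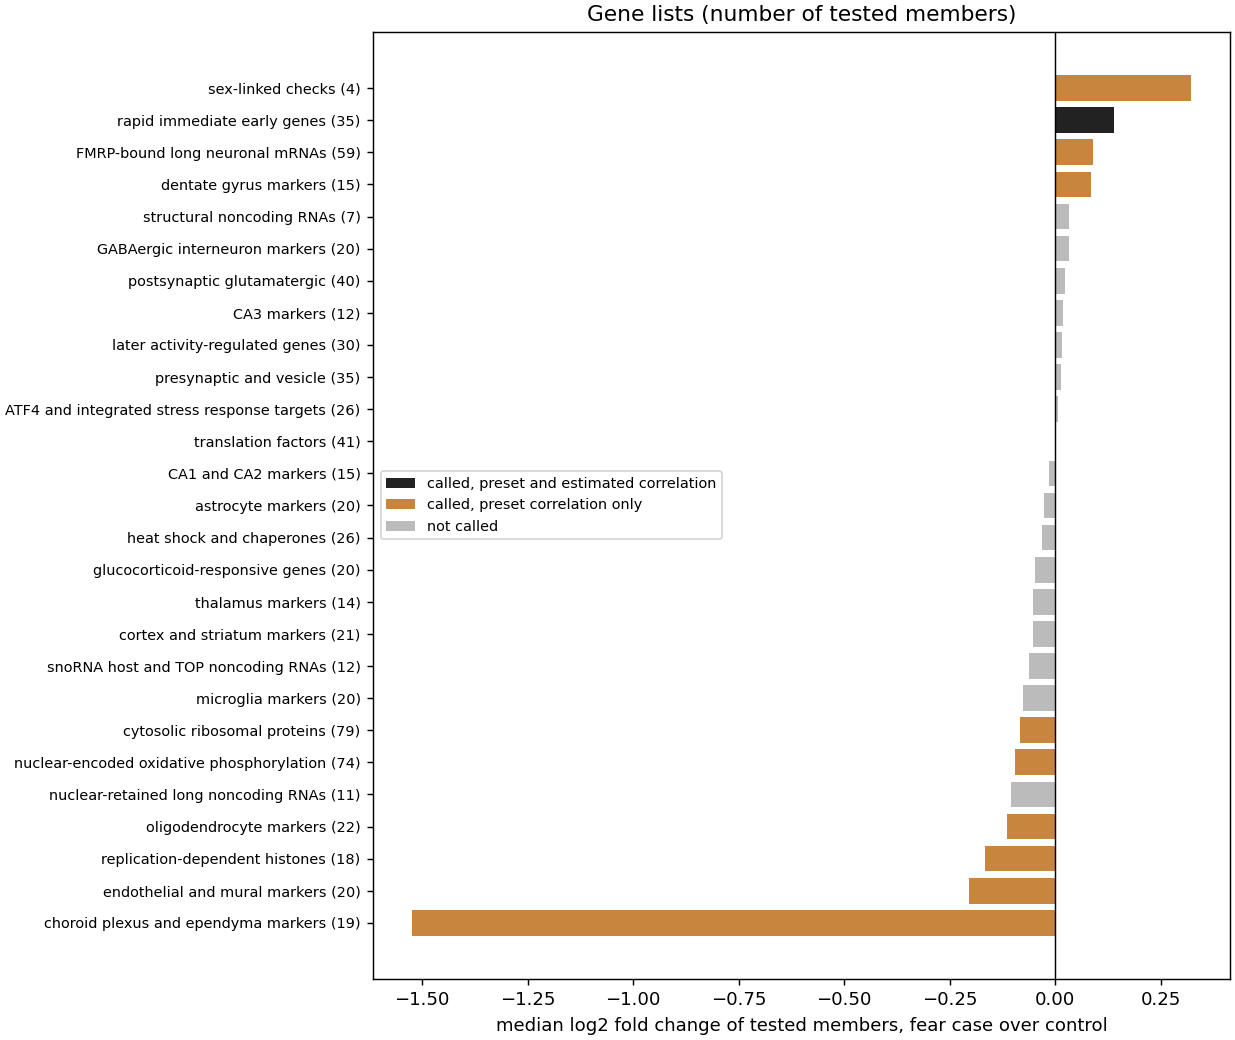
Median log2 fold change of fear case over control (horizontal axis) for each of the 27 tested gene lists, with the number of tested members in parentheses. Black marks a call with both the preset and the estimated correlation, brown a call with the preset correlation only and grey no call. The choroid plexus and ependyma list has the lowest median (-1.52), and the rapid immediate early gene list is the only black bar.

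Apart from the dentate gyrus and oligodendrocyte lists given above, lists of neuronal and glial markers were not called. The adjusted p was 0.988 for CA1 and CA2 markers (15 tested), 0.436 for CA3 markers (12 tested), 0.322 for GABAergic interneuron markers (20 tested), 0.890 for astrocyte markers (20 tested) and 0.533 for microglia markers (20 tested). Postsynaptic glutamatergic genes gave 0.195 (40 tested) and presynaptic and vesicle genes 0.369 (35 tested). The postsynaptic list was called without control 1 (adjusted p = 0.0206), and the later activity-regulated list without control 5 (0.0402). Markers of regions next to the hippocampus were not called either, with 0.369 for thalamus markers (14 tested) and 0.237 for cortex and striatum markers (21 tested). Ppp1r1b was the only member called among the latter, over all genes and adjusted over the list alone. Stress lists were not called, with 0.436 for heat shock and chaperones (26 tested), 0.855 for ATF4 and integrated stress response targets (26 tested) and 0.369 for glucocorticoid-responsive genes (20 tested). Translation factors gave 0.988 (41 tested), snoRNA host and TOP noncoding RNAs 0.436 (12 tested) and structural noncoding RNAs 0.436 (7 tested). Except for Ppp1r1b, no member of these 15 lists passed with edgeR, over all genes or adjusted over the list alone, or with DESeq2 or limma-voom. Each list had 0 to 3 members with an unadjusted p under 0.05, and with an estimated correlation their adjusted p ranged from 0.601 to 0.991. Of the blood cell marker list 1 member was tested, and of the mitochondrially encoded list 0, so these lists were not tested.

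The make-up of the libraries was compared by exact two-sided permutation tests over 924 relabellings, whose smallest possible p is 0.00216. After adjustment over 11 measures, 0 differed, and 4 had an unadjusted exact p under 0.05. The share of counts in nuclear-retained long noncoding RNAs was 1.47 ± 0.164% in controls and 2.03 ± 0.276% in fear case (n = 6 each; exact p = 0.00649, adjusted p = 0.0714). Most of this share was Malat1, at 12896 ± 2091 CPM in controls and 18901 ± 2805 CPM in fear case. The share in choroid plexus and ependyma markers was 0.138 ± 0.0561% and 0.0400 ± 0.0532% (exact p = 0.0130, adjusted p = 0.0714), and the fear case mean was 0.0193% without fear case 6. Gene counts were 20.2 ± 1.32 M and 25.9 ± 9.13 M (exact p = 0.0325, adjusted p = 0.119). The first principal component of log2 CPM held 18.5% of the variance and differed between the groups (exact p = 0.0108), with fear case 6 on the control side. Its largest loadings belonged to Ttr, Slc4a5 and Folr1 toward the controls and to Fos and Npas4 toward fear case. The second held 12.8% and did not differ (exact p = 0.719). Leaving out fear case 1, fear case 3 or fear case 6 brought 2 measures past the adjusted threshold in each case.

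Sex-linked genes were examined as a check of the libraries. Xist, expressed from the inactive X chromosome of females, had 1 to 16 counts in every library, and the Y-linked genes Uty and Ddx3y had 489 to 1340 and 866 to 2772 counts. Kdm5d and Eif2s3y had 355 to 1191 and 123 to 603 counts in 11 libraries but 1 and 0 counts in control 6. With 0 counts, the library allows up to 3 counts of Eif2s3y, a limit that covers counting error only. The list of sex-linked checks was called higher in fear case with the preset correlation (4 tested, 0 passing; adjusted p = 0.0136, and 0.245 with an estimated correlation). That call ended without fear case 6 (adjusted p = 0.110).

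**Figure D4:**
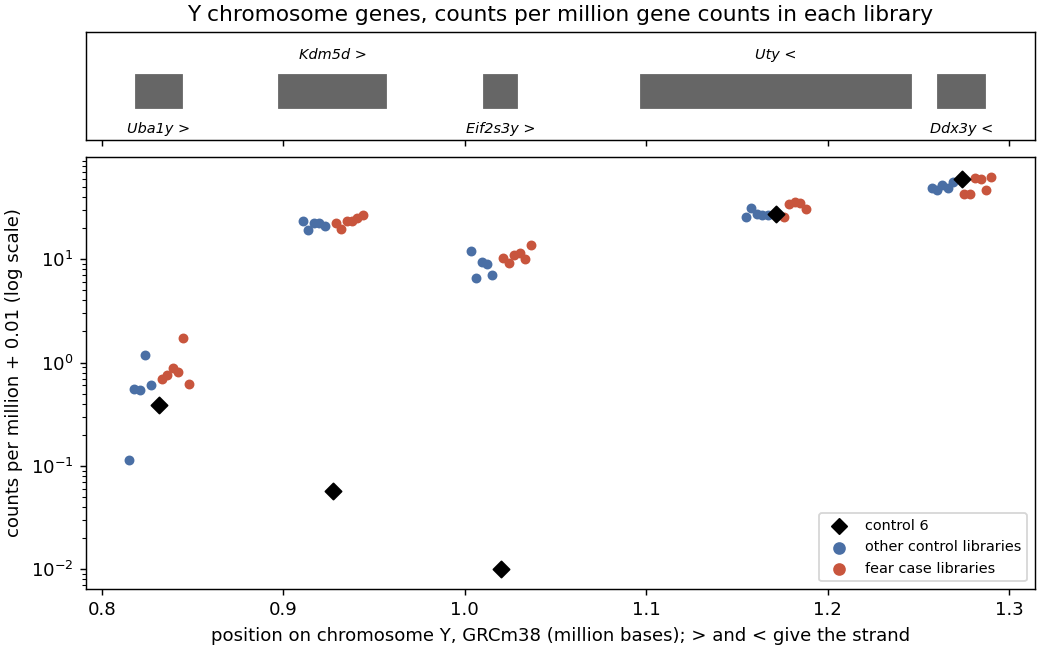
Upper panel, positions of 5 genes on chromosome Y in GRCm38 (megabases), with > and < for the strand. Lower panel, CPM of gene counts plus 0.01 (log scale) of each gene in control 6 (diamonds) and in the other 11 libraries (circles, spread sideways); control 6 stands apart from the others for Kdm5d (1 count) and Eif2s3y (0 counts).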

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

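The tests of the lower genes and of Nxn with the score, of Malat1, of the sex of control 6 and of a deletion on chromosome Y were chosen only after the result was seen. Chance sets apart about 5% of the groups of 6, or 10 of the 200 tested here. In these data 23 values stood apart from the other 5 libraries of their group. Some of these share reads, as Rn45s is part of the structural noncoding RNA share and Kl of the choroid plexus share. The excess over chance is therefore not a test, because the 23 values are not independent.

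Fear case 6 held 11 of them. It was highest in its group for gene counts (44.2 M), the share of the 10 most abundant genes (18.2%), the share of structural noncoding RNAs (12.8%), Rn45s (137847 CPM), the share of choroid plexus and ependyma markers (0.144%), Kl (58.9 CPM) and Slc4a2 (26.6 CPM). It was lowest for Rps10 (82.7 CPM), Ndufa1 (19.99 CPM), Uqcrq (83.6 CPM) and Stx1a (105 CPM). Fear case 1 was highest for Junb (77.8 CPM), Egr1 (290.4 CPM), Nr4a1 (55.7 CPM) and Sdhc (54.9 CPM) and lowest for Cldn5 (0.426 CPM). Fear case 3 was highest for Gfap (165 CPM). Among controls, Ucp2 was highest in control 5 (44.3 CPM) and Sult1a1 in control 3 (7.51 CPM). Maf was lowest in control 1 (14.6 CPM), Cdkn1a in control 4 (1.11 CPM), Rpph1 in control 5 (451 CPM, against at least 6667 CPM in the other controls) and Kdm5d in control 6 (0.0485 CPM).

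Lower choroid plexus markers and the 8 lower genes were weighed together. Among the 6 controls alone, the 17 epithelial markers varied together, with a median correlation of 0.844 between a marker and the mean of the others. It was 0.0284 for 1000 random lists matched on expression. A varying amount of this tissue in the dissected hippocampi would give this, but so would a joint change of these genes within the tissue. Variation among controls also does not decide what lowered the markers in fear case. A fall of these transcripts in proportion to the neuronal response was not seen, since the immediate early gene and choroid plexus scores had r = 0.158 over the 6 fear case libraries (exact p = 0.781, adjusted 0.781 over 2 relations; rho = 0.2, exact p = 0.714; r = 0.135 without the 2 farthest libraries), but 6 libraries leave it open. With the score as a covariate the median log2 fold change of the 8 genes shrank by 47.5%, from -0.84 to -0.44 (median SE 0.16 in both fits). The SE grew for Nxn (0.12, and 0.18 with the score), Tekt1 (0.20, and 0.27) and 5930403L14Rik (0.12, and 0.14). Shrinkage was therefore not the only change behind the lost calls. The higher gene Fosb lost its call too (1.03, SE 0.17, and 0.92, SE 0.23, with the score). A lost call is thus not by itself evidence of a tissue share. For Nxn the values argue against a choroid plexus share as the cause, since its log2 fold change kept its size with the score (-0.82, SE 0.18). It also stood at 7.08 CPM in fear case 6, below the lowest control (10.04 CPM). In that library Msx1 (14.1 CPM, lowest control 16.8), Ppp1r1b (48.4, lowest control 57.3) and 5930403L14Rik (23.7, lowest control 24.4) lay below all controls too. Tekt1, Ucp2 and Slc4a2 did not. The log2 fold changes of these genes shrank with the score, unlike that of Nxn. For the other 7 genes a tissue share and a response to the exposure cannot be told apart, because the score differs between the groups. Whether tissue collection differed between the groups, or the exposure itself acted on the choroid plexus in all mice, stays untested.

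Malat1 rose by 0.55 on the log2 scale. Nuclear RNA carried into the pellet should raise the other nuclear-retained long noncoding RNAs by about as much, but the median of the 10 others was -0.12 (SD 0.21), although one of them, Kcnq1ot1, ran with Malat1 at 0.43 (SE 0.13, adjusted p = 0.348; 5 of 6 fear case libraries above all controls). The median argues against carry-over but cannot rule it out without input RNA. The depth of fear case 6 is not the source of the rise, since the log2 fold change of Malat1 without that library was 0.50. A hypothesis that stays open is more Malat1 in cytoplasm or in dense particles after exposure, which the files cannot test without input RNA.

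Kdm5d and Eif2s3y were missing in control 6 (1 and 0 counts, where the mean level of the other libraries would give 482 and 211). A female or a swapped female sample is excluded by Uty at 28.5 CPM in that library. Scattered loss of transcripts is argued against by 0 other genes with at most 1 count there and at least 5 CPM in each other library. A deletion between Uba1y and Uty (844225 to 1096860 in GRCm38) stays open and was not put to an independent test: Kdm5d and Eif2s3y are themselves the 2 expressed genes there, so their highest count of 1 restates the pattern. No biological explanation tied to the groups was tested, and without control 6 the list of sex-linked checks was still called.

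Chance was weighed with 100 splits of the 12 libraries into 6 and 6. The real split called 15 genes, a number reached by 2 of the 100 with the real one included. Such a count was rare among the splits, but chance is not excluded. The other split, which set controls 1 to 5 and fear case 6 against the rest, called 46 genes. It differs from the real split only by the exchange of control 6 and fear case 6. It therefore cannot show whether the number of calls is particular to the group labels. Its adjusted p was 6.8e-48 for the choroid plexus list and 5.9e-13 for the rapid immediate early gene list. Which genes it called was not examined. For the rapid immediate early gene list only the real split (1 of 100) gave so small an adjusted p (3.3e-30, next 8.9e-20). For the choroid plexus list 3 of 100 did so (8.1e-32, smallest other 6.8e-48). The 10 lists called with the preset correlation were reached or passed by 30 of 100 splits (highest other 15), so chance cannot be excluded for their number.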

How the results depend on the processing

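The tests with the choroid plexus score as a covariate, with fear case 6 thinned, and without both control 6 and fear case 6 were chosen only after the result was seen; the other choices and their alternatives were fixed before the data were examined. The 15 genes called depended on the choices as follows. With library size only in place of TMM, 33 genes were called, 7 higher and 26 lower. DESeq2 called 63 (13 higher, 50 lower), limma-voom 12 (5 lower) and limma-voom with sample weights 129 (12 higher, 117 lower). Without a filter on low counts 37 were called (11 higher, 26 lower), and with at least 1 CPM in 6 libraries 11 (4 lower). A surrogate variable, which mainly set fear case 6 apart, gave 141 (14 higher, 127 lower), and the library number as a covariate 11 (4 lower). The choroid plexus score left 5 higher and 0 lower, and leaving out control 6 and fear case 6 gave 110 (12 higher, 98 lower). Leaving out one library at a time gave 9 to 128 genes called, 6 to 12 higher and 3 to 116 lower, with the highest counts without fear case 6. Thinning fear case 6 to 21.2 M counts left 15 called, 14 of them shared, so its depth was not what held the calls down; the cause was not tested further. Fos, Npas4, Arc, Btg2 and Junb were called with all 28 alternatives.

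Libraries with the same replicate number had correlations from -0.171 to 0.0468, with 0 of 6 pairs above 0.1, so they were not treated as paired. For 2 of the 6 controls the fear case library of the same number was the most alike. With the replicate block 18 genes were called, 7 higher and 11 lower, and 13 were shared.

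Of the lists, 10 were called, 5 with the surrogate variable, 1 with an estimated correlation, 1 with fry and 6 to 12 with one library left out. With the surrogate variable the adjusted p of the ribosomal protein, oligodendrocyte and histone lists became 0.113, of oxidative phosphorylation 0.166 and of the sex-linked checks 0.103. With one library left out the adjusted p of the rapid immediate early gene list stayed between 3.1e-36 and 6.5e-23. The choroid plexus list gave an adjusted p of 0.0547 with an estimated correlation and 0.0568 with fry, and with its own score as a covariate 0.799 by construction; the covariate also ended the endothelial and mural call (0.343).

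Results near 0 changed sign. Ddx3y moved from a log2 fold change of 0.05 to -0.0168 with the surrogate variable and -0.0393 without fear case 6. Rn45s moved from 0.11 to -0.20 with sample weights, -0.24 with the surrogate variable, -0.14 without control 6 and fear case 6, and between -0.25 and 0.21 with one library left out. Rpph1 moved from -0.07 to 0.29 with limma-voom, 0.45 with sample weights, 0.16 with the surrogate variable, 0.0712 without control 6 and fear case 6, and between -0.32 and 0.0730 with one library left out. Lists that were not called turned direction in the same way. The adjusted p of translation factors was 0.685 with library size only, 0.986 with the filter of 1 CPM, 0.790 with fry and 0.548 to 0.966 with one library left out. With one library left out it was 0.394 to 0.977 for CA1 and CA2 markers, 0.136 to 0.957 for astrocyte markers, 0.144 to 0.932 for microglia markers, 0.448 to 0.991 for ATF4 targets, 0.0260 to 0.986 for nuclear-retained long noncoding RNAs and 0.154 to 0.754 for structural noncoding RNAs. Each of these ranges covers all 12 libraries left out in turn, and only some turned the direction. These numbered 6 for translation factors, 6 for CA1 and CA2 markers, 4 for astrocyte markers and 4 for ATF4 targets. They numbered 2 for microglia markers, 1 for nuclear-retained long noncoding RNAs and 1 for structural noncoding RNAs. With the choroid plexus score the adjusted p was 0.122 for astrocyte markers and 0.636 for heat shock. It was 0.858 for glucocorticoid-responsive genes and 0.718 for structural noncoding RNAs with that score. Without control 6 and fear case 6 it was 0.760 for ATF4 targets. Of the 11 library measures, 0 were called, and 0 to 2 with one library left out. Depth limits the tests to genes with about 10 counts in 6 libraries, so a change in rarer transcripts would be missed.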

Other observations

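The tests of the motile cilia and leptomeningeal lists were chosen only after Tekt1 and Rsph4a had been seen among the lowest genes; the test of Fos against Arc was planned before its result was seen. Genes of motile cilia, the beating protrusions of ependymal and choroid plexus cells, lay lower in fear case as a group. Of 52 tested members, 42 had a negative log2 fold change and 1, Tekt1, was called; the median was -0.34 (adjusted p = 1.8e-13 over the 2 lists, and 0.00925 with an estimated correlation). Examples are Cfap52 (log2 fold change -1.09, adjusted p = 0.0724), Rsph4a (-0.70, adjusted p = 0.0722), Rsph1 (-0.79, adjusted p = 0.179) and Foxj1 (-0.66, adjusted p = 0.0759), the last of which the choroid plexus list also holds. Without Tekt1 and Rsph4a, which prompted the list, and Foxj1, the other 49 members had a median of -0.33 with 39 negative (adjusted p = 4.4e-10, and 0.0197 with an estimated correlation). With the choroid plexus score as a covariate the median of these 49 shrank to -0.0481 (adjusted p = 0.319), and that of all 52 to -0.0882 (adjusted p = 0.0879). A candidate explanation is that ciliated cells of the ventricle wall and choroid plexus differed in share along with the choroid plexus epithelium.

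Genes of leptomeningeal fibroblasts, the cells of the thin membranes that cover the brain, had a median log2 fold change of -0.18 over 27 tested members, of which 23 were negative and 0 called (adjusted p = 0.000174, and 0.163 with an estimated correlation). The transporter gene Slc13a4 stood at -0.97 (adjusted p = 0.348) and the forkhead gene Foxc1 at -0.78 (adjusted p = 0.148), whereas the collagen-binding proteoglycan gene Dcn, also a CA1 and CA2 marker, stood at 0.26 (adjusted p = 0.769). With the score the median was -0.16 (adjusted p = 0.0690). Whether meningeal tissue varied together with the choroid plexus could not be settled, since the median moved little and the list did not pass with an estimated correlation.

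Whether mice with more Fos on polyribosomes may also have had more Arc was tested over the 6 fear case libraries. Pearson's r of log2 CPM was 0.910 (exact p = 0.0597, adjusted 0.119 over 2 relations) and Spearman's rho 0.486 (exact p = 0.356, adjusted 0.711). Without fear case 1 and fear case 5, the farthest in Fos, r was -0.983 over 4 libraries, so the relation rests on those 2 libraries.

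Of 14564 genes, 87 had groups that did not overlap (0.597%), where chance gives 0.216% or 31.5 genes.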
